A study of Sus scrofa with 50 samples.

How the data were processed

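Poly(A) RNA of heart, kidney, liver, lung and spleen from 10 Korean minipigs was sequenced as stranded mRNA libraries, 50 in all. ET-type animals were S0235, S0242, S0276, S0309 and S0326, and L-type animals S0349, S0355, S0377, S0384 and S0385; each gave all 5 tissues. The authors deposited TPM, a length-normalised share of all transcripts, of 57085 assembled transcripts, in columns that each sum to 1e+06. Reads were trimmed with Trimmomatic 0.36 and quantified with Salmon 1.10.0 per the submitters' processing notes, which also list the build Sscrofa11.1. Transcript names give the tissue and type of the assembly they come from, and these cover 10 tissues; 89 transcripts were 0 in all libraries. The other 5 tissues were not analysed here, since the series holds no libraries of them. Read counts were not given, so the depth per library is unknown and no count model was used.

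The deposited annotation gives the best Swiss-Prot match of 63.9% of the transcripts, with a median identity of 91.2%. TPM was summed over transcripts that share an entry, which gave 14532 entries, and the other transcripts were kept on their own, for 35133 genes in all. Of the entries, 36.8% rest on 1 transcript, 50.4% are of the human protein and 5.98% of the pig protein. A gene so defined pools close relatives: LORF2, a protein of a mobile element, holds 2412 transcripts. A long transcript split by the assembly, or 1 matched to a paralog, is not told apart.

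Each tissue was fitted alone with limma 3.58.1 (trend, empirical Bayes) in R 4.3.3 on log2(TPM + 1), 5 against 5 animals, for genes with a mean of at least 1 TPM. Benjamini-Hochberg adjusted p below 0.05 was called. A further fit compared each animal's mean over its 5 tissues. The interaction of type and tissue was tested on all 50 libraries with the animal as replicate block, by an F test. Genes higher in a tissue needed an adjusted p below 0.05, a log2 difference of at least 1 from the mean of the other tissues, and a lowest group mean above every other tissue's. Fixed lists of genes, 35 in all, covered tissue markers, cell types, metabolism, growth, immunity, stress and grafting; 524 of 602 symbols were matched to entries. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Fry was also used, which tests each list by itself rather than against the other genes. Single measures were compared by exact 2-sided permutation tests, for which 5 against 5 animals allow no p below 0.00794. Tables and figures used data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

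The comparisons, the lists, the settings to vary and the rule for naming genes were fixed before the data were examined. Named are, in each type fit, the 10 genes with an entry and the largest log2 difference in each direction among those that passed with groups that did not overlap; where fewer than 5 passed, the 5 with the smallest p in each direction are given as not passing. Added are list members that passed, 2 to 4 with the smallest p, or else the 2 with the smallest p; the 5 highest genes per tissue; and the 10 smallest p of the interaction. Genes of grafting, antigen presentation and growth could be given as values. In heart, 1 gene that the rule names is left out of the text. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, a fold of at least 2, median-ratio and quantile scaling, mitochondrial and the 10 highest genes left out, robust limma, transcripts in place of genes, 1 animal left out at a time, and all libraries in 1 fit with the animal as replicate block. Haemoglobin left out, and the kidney library of S0235, the kidney or the spleen libraries left out, were chosen after seeing the data.

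Labels were checked by the pairing of tissues. After tissue and type means were removed, libraries of the same animal had a mean r of 0.251 across genes over 100 pairs of libraries, 96 of them above 0.1, against -0.0631 over 400 pairs from different animals of one type; no library occurred more than once. Each fit was tested on simulated data, with 100 genes changed by 1 and 100 by 3 on the log2 scale among values drawn around each gene's mean with its own spread. For a change of 1 the fit recovered 36% in heart, 1% in kidney, 14% in liver, 30% in lung, 47% in spleen, 86% across tissues and 12% of interactions. For a change of 3 these shares were 99%, 84%, 92%, 89%, 91%, 100% and 88%. False calls made up 3.41 to 8% of the calls. Each gene and library was drawn independently, with no effect shared by the tissues of an animal. In the real data such an effect was present, so the 86% across tissues and the share of false calls may be too favourable. In kidney, genes set higher in the tissue by 1.5 were recovered in 95% and by 3 in 99%.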

Results

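Heart, kidney, liver, lung and spleen of 10 Korean minipigs, 5 of the ET type and 5 of the L type, gave 50 libraries, 1 per animal and tissue. The values were TPM of 57085 transcripts assembled across both types. A gene below is 1 Swiss-Prot entry, summed over the transcripts whose best protein hit it was, and is written with that entry's short name. Differences are ET-type minus L-type on log2(TPM + 1), given with their SE, and group values are mean TPM ± SD with n = 5 animals per type. Adjusted p-values of single genes come from limma. The depth behind the values was not given, so no counting interval could be attached to them, and the sex of the animals was not in the labels.

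Tissue set the libraries apart. The first principal component carried 29.9% of the variance and the second 22.1%, and 49 of 50 libraries were closest to the mean of their own tissue, all but a kidney library of ET-type S0235. Averaged over genes, tissue took 61.7% of the variance, type 2.76%, the interaction of type and tissue 4.94%, animals within a type 10.7% and the rest 19.9%. Per degree of freedom these shares were 15.4%, 2.76%, 1.23%, 1.34% and 0.621%, so that the interaction and the animals both lay above the rest. Kidneys of ET-type animals held 23766 ± 944 genes at 1 TPM or more against 25984 ± 697 in L-type (exact permutation p = 0.00794, adjusted over 5 tissues 0.0198). Spleens held 20673 ± 1012 against 24437 ± 1520 genes (exact permutation p = 0.00794, adjusted 0.0198). Both p-values are the smallest that 5 against 5 animals allow. In lung the numbers were 27108 ± 245 and 28129 ± 782 (exact permutation p = 0.0476, adjusted 0.0794), and in lung, heart and liver the ranges of the types overlapped.

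**Figure D1:**
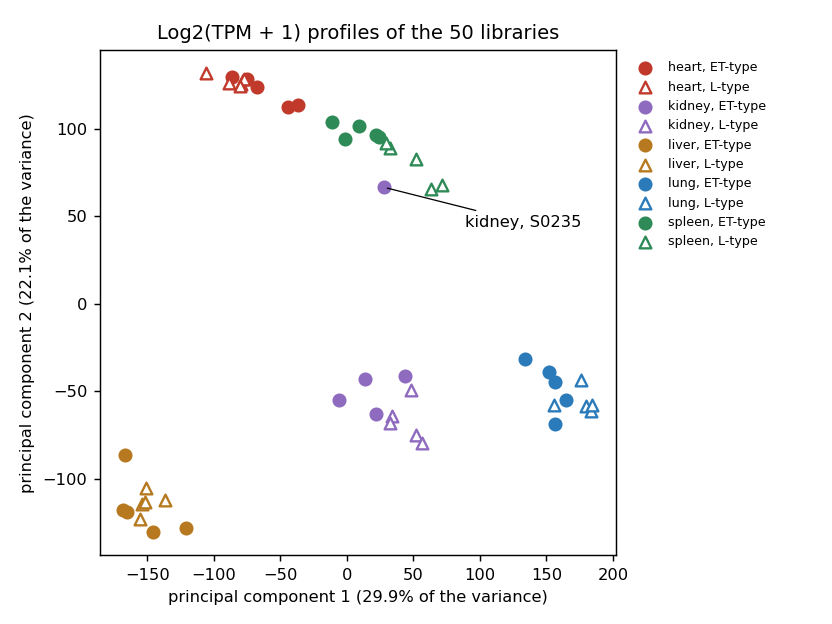
First and second principal components of log2(TPM + 1) for the 50 libraries, with the share of variance on each axis. Filled circles are ET-type and open triangles L-type animals, colours are tissues, and the kidney library of ET-type S0235 lies beside the spleen libraries.

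Genes of tissue function had the largest log2 differences between a tissue and the other 4, and are named in that order, which is not the order of TPM. In heart, MLRV, the ventricular myosin light chain, reached 37218 ± 14632 TPM against 3.81 ± 10.9 TPM in the other 4 tissues, and TNNT2, the cardiac troponin T, 6799 ± 2009 TPM against 1.16 ± 3.66 TPM. In liver, ALBU (albumin) stood at 115169 ± 33447 TPM against 4.82 ± 8.98 TPM, and the fibrinogen chains FIBB and FIBA and the apolipoproteins APOH and APOC3 followed. By log2 difference lung was led by UTER, a secretory protein of the airway, with 19726 ± 15572 TPM against 1.20 ± 0.547 TPM, followed by the surfactant proteins PSPC and PSPB, CBR2 and SFTPA. By log2 difference kidney was led by AADAT, an aminotransferase, with 1061 ± 814 TPM against 0.180 ± 0.139 TPM, then by S6A18, UROM, KLK and S22AC. By log2 difference spleen was led by HBA, the haemoglobin alpha chain, with 47372 ± 38168 TPM against 53.3 ± 72.7 TPM, and HBB, IGM, HEM0 and ITAD. All of these values are means ± SD over 10 libraries against 40.

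By limma, 1356 genes were higher in heart than in each other tissue, 2019 in kidney, 2031 in liver, 6277 in lung and 2103 in spleen, out of 29796 tested. Fixed marker genes passed in 14 of 14 cases for heart, 14 of 15 for kidney, 14 of 15 for liver, 13 of 15 for lung and 11 of 15 for spleen. Without the kidney library of S0235, kidney had 2697 genes and 15 of 15 markers. With median-ratio rescaling heart had 2497, liver 3187 and lung 2927 genes.

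One kidney library, of ET-type S0235, held few kidney transcripts. UROM, made by the thick ascending limb, stood at 0.179 TPM against 1628 ± 2014 in the other 9 kidneys, and AQP2, the water channel of the collecting duct, at 0.00956 against 480.5 ± 185. The median kidney marker was at 0.281% of its mean in the other kidneys, 12 of 15 markers were below 1%, and the highest was at 21.3%. Genes of lymphocytes and of lymphoid stroma were high there: CCL21 at 1648 TPM, CCL19 at 1247, CD3E at 553, CXL13 at 320.3, CCR7 at 197 and CD20 at 119.5, where no other kidney had CD20 above 0.152. Across genes, its profile had r = 0.633 with the mean of the other kidneys and 0.834 with that of the spleens; genes are not independent replicates. CCL21 and CCL19 were picked after the values were seen, and the other genes come from the fixed lists. The library was kept in every fit and left out as an alternative.

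**Figure D2:**
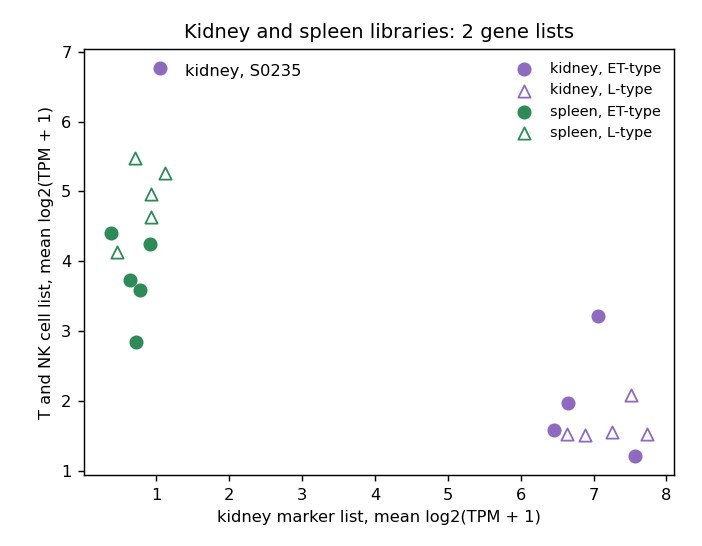
Mean log2(TPM + 1) of the kidney marker list on one axis and of the T and NK cell list on the other, 1 point per kidney or spleen library. The kidney library of ET-type S0235 has a kidney mean as low as the spleens and a T and NK cell mean above all of them, apart from the other 9 kidneys.

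In heart, CGNL1, a protein of cell junctions, was higher in ET-type animals, at 8.401 ± 0.992 against 3.22 ± 0.5002 TPM (1.16 ± 0.15, adjusted p = 0.0378), with all 5 ET-type animals above all 5 L-type. Of the other 4 passing units, 1 gene higher in ET-type is not named here and 3 were transcripts without a protein hit. Lymph.ET.NODE_5956 was higher in ET-type (2.07 ± 0.339 against 0.167 ± 0.167 TPM), while Lung.L.NODE_218900 (0.768 ± 1.56 against 30.4 ± 15.7 TPM) and Brain.L.NODE_89446 were lower, and they were named after their values were seen. Among genes that did not pass, vimentin (VIME), the filament of mesenchymal cells, had 499 ± 183 against 157 ± 35.2 TPM (adjusted p = 0.0731). ACADV, the very long chain acyl-CoA dehydrogenase, had 111 ± 37.2 against 279 ± 42.6 TPM (-1.37 ± 0.24, adjusted p = 0.0863). LXN and SLIT2 had 2.06 and 1.33, PAFA -1.52, DC1I1 -1.06, CASQ1 -0.93 and SNG2 -0.74 on the log2 scale. By limma 5 of 21014 genes passed, 3 higher and 2 lower in ET-type, and 4670 had an unadjusted p below 0.05. Median-ratio or quantile scaling gave 6, of which 33.3% were higher in ET-type instead of 60%. Groups did not overlap for 6.61% of the genes with an entry, against an average of 0.794% over all splits of the animals into 5 and 5. Genes vary together between animals, and the share was not counted split by split. Here and in the fits below, the gap to that average is thus no measure of an effect of type. The count became 2162 without ET S0242, 8 without L S0349, 3 without ET S0309 or L S0385, and 0 without ET S0276, S0326 or L S0355, S0377, S0384, while CGNL1 had 0.0638 to 0.169 as adjusted p where a library left out ended its call, which was each but ET S0242 and L S0349. In 1 fit of all libraries with the animal as replicate block, 718 heart genes passed. With a pseudocount of 0.1 the count was 0, so CGNL1 lost its call there too.

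By camera at a preset correlation, the list of fatty acid oxidation lay lower in ET-type hearts and that of extracellular matrix higher. None of the calls given next held with an estimated correlation (adjusted p = 0.400 for each). Of the 19 measured genes of mitochondrial fat burning, 0 passed over all genes and 13 were lower adjusted over the list alone. The list lay -0.94 log2 relative to all genes, camera adjusted p = 1.07e-08. ECHB, a subunit of the trifunctional enzyme, had 131 ± 60.6 against 403 ± 53.8 TPM (-1.75 ± 0.32). Respiratory chain genes of the nucleus lay -0.73 log2 relative to all genes, camera adjusted p = 2.50e-07, with COX5A at 385.2 ± 222 against 769 ± 72.5 TPM and 0 of 24 members passing by limma. The hearts of ET S0276, S0309 and S0326 carried this, with list means of 8.81, 8.01 and 8.09 and 43.5 to 47.1% of TPM in mitochondrial transcripts. ET S0235 and S0242 had list means of 9.37 and 9.502, within the range of L-type hearts (9.29 to 9.53). The 14 heart muscle genes lay -0.79 log2 relative to all genes, camera adjusted p = 2.36e-04, with MYL3 at -1.26 ± 0.38 and MYH7 at -1.12 and none past the test. The list mean of ET S0242, 10.83, lay above every L-type heart (10.19 to 10.55), and the other 4 ET-type hearts lay below (9.21 to 9.97). In the other direction, 11 of 13 matrix genes were higher adjusted over the list alone and 0 over all genes. This list lay 1.31 log2 relative to all genes, camera adjusted p = 2.50e-07, with collagen CO1A2 at 90.1 ± 36.01 against 28.6 ± 16.9 TPM and fibronectin (FINC) at 20.1 ± 7.43 against 6.99 ± 3.21 TPM. Antigen presentation genes lay 0.74 log2 relative to all genes, camera adjusted p = 4.79e-07 (11 of 19 adjusted over the list alone), and complement genes 0.77 log2 relative to all genes, camera adjusted p = 6.37e-05 (11 of 17), with CO3 at 61.9 ± 27.5 against 19.3 ± 6.54 TPM. ET S0276, S0309 and S0326 carried antigen presentation, with list means of 6.04 to 6.11, while ET S0242, at 4.50, lay below every L-type heart (4.57 to 4.97). ET S0242 also lay within the L-type range for complement, grafting, endothelial and red cell genes. Genes that matter in pig-to-human grafting lay 0.64 log2 relative to all genes, camera adjusted p = 1.30e-05 (9 of 15), with ENTP1, an ectonucleotidase of vessel walls, at 8.65 ± 1.91 against 3.30 ± 1.23 TPM. Endothelial genes lay 0.70 log2 relative to all genes, camera adjusted p = 7.17e-05 (4 of 12), with MUCEN at 43.0 ± 14.3 against 18.2 ± 6.44 TPM and PECA1 at 0.80. Blood content moved with the groups: red cell genes lay 0.94 log2 relative to all genes, camera adjusted p = 0.00468 (4 of 8), HBB had 411 ± 318 against 48.99 ± 37.9 TPM, and haemoglobin took 0.0538 ± 0.0410% of TPM against 0.00703 ± 0.00529% (exact permutation p = 0.0159, adjusted 0.0794).

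Interferon response genes (+0.53, adjusted p = 0.00839), macrophage genes (+0.26, 0.0235), proliferation genes (+0.38, 0.0253) and acute phase genes (+0.33, 0.0437) were also called higher in ET-type hearts. Single libraries ended these calls: the adjusted p was 0.417 without ET S0276 for interferon response, 0.0524 to 0.153 without ET S0235, S0276 or L S0384 for macrophages, 0.0734 to 0.0950 without L S0355, S0384 for proliferation and 0.0584 to 0.144 without ET S0235, S0242, S0326 or L S0349, S0355, S0377 for acute phase genes. None of the 13 heart lists held with an estimated correlation: camera gave adjusted p = 0.400 with an estimated correlation for all but interferon response (0.696) and macrophages (0.606).

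**Figure D3:**
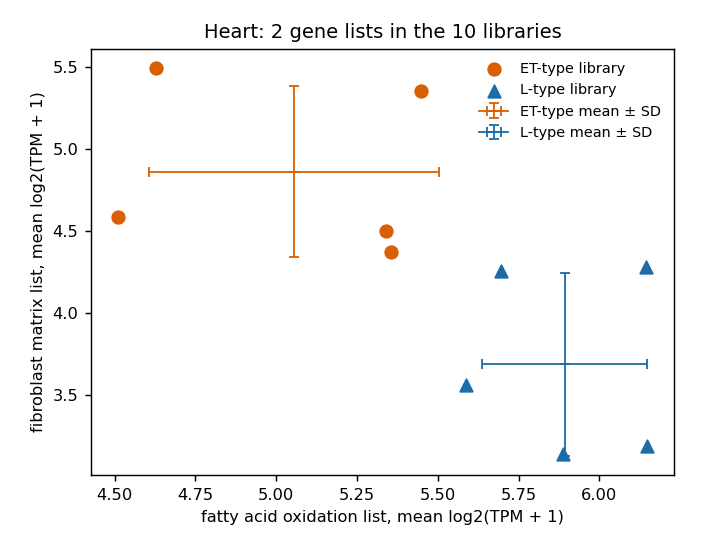
Mean log2(TPM + 1) of the fatty acid oxidation list and of the matrix list in each heart library, with the group mean and SD (n = 5 animals per type). ET-type hearts sit lower for fatty acid oxidation and higher for matrix.

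No gene passed between the kidneys of the types in the fit of kidney alone. EDN2, a vasoconstrictor peptide, had 0.547 ± 0.426 against 3.55 ± 0.9851 TPM (-1.57 ± 0.29, adjusted p = 0.436), EGR1, an immediate early transcription factor, 18.0 ± 4.82 against 85.4 ± 75.3 TPM (-1.92 ± 0.44), and lactoferrin (TRFL) -2.28 ± 0.51. H3C and SYNEM had -1.75 and -1.47. With higher ET-type means, KITH, a thymidine kinase of dividing cells, had 8.22 ± 10.1 against 1.27 ± 0.703 TPM (1.62 ± 0.51), CPXM1 1.78, OTULL 1.33, E2F1 1.13 and CCL3 1.12, and no adjusted p in either direction was below 0.153. The library of S0235 raised some of these: without it KITH had 1.11, OTULL 0.95, E2F1 0.80 and CCL3 0.94. By limma 0 of 27303 genes passed and 2301 had an unadjusted p below 0.05. Groups did not overlap for 1.0% of the genes with an entry, against an average of 0.794% over all splits. The median gene lay 0.27 lower in ET-type on the log2 scale (-0.27). Leaving out ET S0235 gave 1 gene and leaving out ET S0309 gave 3. In 1 fit of all libraries with the animal as replicate block, which pools the spread of the tissues, 1369 kidney genes passed, 5.19% of them higher in ET-type.

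The kidney lists were led by genes of immune cells, and the odd library S0235 carried much of this. Camera with an estimated correlation called none of them (lowest adjusted p = 0.405). T and NK cell genes lay 1.62 log2 relative to all genes, camera adjusted p = 3.54e-12, with CD3Z at 112 ± 223 against 6.05 ± 1.92 TPM (1.83, and 0.73 without S0235). Without S0235 the list lay 0.83 relative to all genes (camera adjusted p = 7.82e-07). B lymphocyte genes of the spleen list lay 1.46 log2 relative to all genes, camera adjusted p = 8.38e-10, and without S0235 too few of them were measured for a test. Proliferation genes lay 1.12 log2 relative to all genes, camera adjusted p = 2.83e-12, and without S0235 0.37 (0.00311). Relative to all genes, macrophage genes lay 0.94 higher (camera adjusted p = 4.85e-07, without S0235 0.57 and 1.87e-04) and antigen presentation genes 0.70 (4.85e-07, without S0235 0.14 and 0.0386). On the same scale B and plasma cell genes lay 1.26 higher (1.77e-06, without S0235 0.29 and 0.0488) and complement genes 0.54 (2.96e-04, without S0235 0.37 and 0.00232). Without S0235 the median of all genes lay at -0.28, so the median antigen presentation gene was then lower in ET-type. Endothelial genes lay -0.68 log2 relative to all genes, camera adjusted p = 3.69e-05, with TIE2, the angiopoietin receptor, at 8.17 ± 1.90 against 17.7 ± 4.70 TPM; without S0235 they lay at -0.35 (0.00112). Immediate early genes lay at -0.68 (3.38e-04; without S0235 -0.75, 3.11e-04), the heart list at -0.76 (2.96e-04; -0.54, 0.0229) and fatty acid oxidation genes at -0.35 (1.80e-04; -0.18, 0.0249). Kidney marker genes lay at -1.21 (0.0355), with CUBN, a receptor of the proximal tubule, at 12.1 ± 7.199 against 29.4 ± 5.50 TPM (-1.69, and -0.92 without S0235). Without S0235 the list's difference was gone (-0.03, adjusted p = 0.823), and without L S0355 or S0377 the adjusted p was 0.0720 and 0.0668. The interferon list, 0.57 higher (4.12e-05), also lost its call without S0235 (0.05, 0.405).

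Weaker kidney lists changed with single libraries. No kidney call held with an estimated correlation: camera gave adjusted p = 0.405 with an estimated correlation at the lowest, and 0.728 at the highest for kidney markers. Skeletal muscle genes were at -0.29 (adjusted p = 0.0337, and 0.0829 to 0.3197 without ET S0235, S0242 or L S0355, S0384, S0385). The other 4 were higher relative to all genes, with medians or means near 0 or below: cholesterol synthesis genes 0.22 (median -0.05, adjusted p = 0.0355, and 0.0766 to 0.308 without ET S0242, S0309 or L S0349, S0355, S0384), and lipogenesis genes 0.26 (median -0.01, 0.0455, and 0.0845 to 0.163 without ET S0242, S0276, S0326 or L S0349, S0355, S0384). Acute phase genes lay 0.18 higher (median -0.08, mean 0.15, 0.0355, and 0.0623 to 0.339 without ET S0235, S0276 or L S0377, S0385). Matrix genes lay 0.26 higher (median -0.01, mean 0.01, 0.0441, and 0.0523 to 0.630 without ET S0235, S0276, S0326 or L S0355, S0377, S0385). Of the members of the 18 called lists, 0 passed over all genes by limma; adjusted over the list alone, 4 heart, 3 skeletal muscle, 2 fatty acid oxidation, 1 endothelial and 1 immediate early gene were lower.

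In liver, all 22 measured enzymes and regulators of cholesterol synthesis had higher means in ET-type animals. The list lay 0.53 log2 relative to all genes, camera adjusted p = 1.76e-10 at the preset correlation. With an estimated correlation it was not called (adjusted p = 0.622). By limma 0 passed over all genes and 2 adjusted over the list alone. IDI1, the isomerase of isoprenoid units, had 1.93 ± 0.44 (adjusted p = 0.335) and lanosterol synthase (LSS) 226 ± 63.5 against 117 ± 23.4 TPM (0.92 ± 0.25). At the preset correlation the call held with any single library left out. Some cytochromes of drug metabolism had higher means without passing, but the fixed list of drug metabolism was not called (-0.06 relative to all genes, mean -0.83, adjusted p = 0.772), with 7 of 18 members above 0. CP242 stood at 455 ± 137 against 124 ± 36.6 TPM (1.86 ± 0.26, adjusted p = 0.0692), CP2CQ at 663 ± 241.6 against 141 ± 67.6 TPM (2.32 ± 0.39) and CP2CI at 4091 ± 2086 against 726 ± 742 TPM (2.78 ± 0.54). CP2E1, which oxidises ethanol, went the other way, at 24.9 ± 42 against 1223 ± 1083 TPM (-5.85 ± 1.5, adjusted p = 0.397). MORC4 and PLAT5 had 1.93 ± 0.27 and 2.02 ± 0.36; PPIF, of the mitochondrial permeability pore, had 31.8 ± 6.19 against 98.6 ± 29.8 TPM (-1.57 ± 0.24) and the serpin SPA11 -1.39 ± 0.21. IF2A, EGFLA and PRR29 had -2.53, -1.81 and -2.03. By limma 2 of 21445 genes passed, both lower in ET-type and without a protein hit: Liver.L.NODE_37905 (0.290 ± 0.123 against 6.35 ± 0.677 TPM, -2.51 ± 0.19, adjusted p = 4.17e-04) and Liver.L.NODE_69788 (0.468 ± 0.490 against 12.8 ± 2.55 TPM, -3.27 ± 0.26, adjusted p = 4.17e-04). They were named after their values were seen, and 1412 genes had an unadjusted p below 0.05. Groups did not overlap for 1.33% of the genes with an entry, against an average of 0.794% over all splits. The count became 15 without L S0355, 9 without ET S0309, 5 without ET S0276, and 3 without ET S0326 or L S0349, S0377, S0384. In 1 fit of all libraries with the animal as replicate block, 374 liver genes passed.

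Genes of glucose metabolism lay -0.30 log2 relative to all genes, camera adjusted p = 0.0108 in ET-type livers, 2 of 17 lower adjusted over the list alone, with F16P1, an enzyme of gluconeogenesis, at 521 ± 156 against 1125 ± 245 TPM (-1.15 ± 0.26); without ET S0326 the adjusted p was 0.0912. With an estimated correlation no liver list held, cholesterol synthesis included: camera gave adjusted p = 0.622 with an estimated correlation for it, and up to 0.679 for the rest. Called lower were also endothelial genes (-0.71, adjusted p = 0.0202, and 0.0555 to 0.152 without ET S0235, S0242, S0276 or L S0349, S0377), complement genes (-0.27, 0.0306, and 0.0570 to 0.167 without ET S0235, S0242, S0326 or L S0377, S0384) and fatty acid oxidation genes (-0.25, 0.0313, and 0.0570 to 0.527 without ET S0276, S0326 or L S0349, S0355, S0384). B and plasma cell genes lay at -0.44 (0.0445, and 0.0534 to 0.108 without ET S0235, S0242, S0276, S0309, S0326 or L S0349, S0355, S0377, S0384). Called higher were red cell genes (0.43, 0.0306, and 0.0534 to 0.297 without ET S0309, S0326 or L S0355, S0384) and genes of the mitochondrial genome (0.50, 0.0429, and 0.0534 to 0.482 without ET S0326 or L S0349, S0355, S0384). Over all genes by limma, 0 members of these lists passed. The growth hormone and IGF list was not called (-0.15, adjusted p = 0.0947); IGF1 had 3.90 ± 3.55 against 2.55 ± 2.20 TPM and GHR, the growth hormone receptor, 78.9 ± 67.5 against 49.9 ± 28.4 TPM.

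Lungs of ET-type animals had lower ABCA3, the lipid pump that loads surfactant into lamellar bodies, at 26.8 ± 3.39 against 83.8 ± 19.8 TPM (-1.57 ± 0.20, adjusted p = 0.0213). CR2, the complement receptor of B cells, stood at 1.34 ± 0.796 against 12.4 ± 6.18 TPM (-2.47 ± 0.33, adjusted p = 0.0228), GIMA5, a GTPase of lymphocyte survival, at 5.10 ± 0.7499 against 13.9 ± 1.38 TPM (-1.29 ± 0.17) and NCTR1, an activating receptor of NK cells, at 0.906 ± 0.558 against 5.15 ± 1.67 TPM (-1.70 ± 0.28). PI3R6, a regulatory subunit of PI3 kinase gamma, stood at 1.43 ± 0.181 against 6.79 ± 0.886 TPM (-1.68 ± 0.18, adjusted p = 0.0150) and SAP25, of a histone deacetylase complex, at 15.3 ± 4.81 against 53.0 ± 8.25 TPM (-1.76 ± 0.21). GALP, GRAP, TB10C and CCL16 fell by 2.59, 1.65, 1.51 and 1.27 on the log2 scale. By limma 62 of 29139 genes passed, 8 higher and 54 lower in ET-type. Of these 15 had an entry, all 15 were lower, and their groups did not overlap. Of all genes with an entry 4.73% had such groups, against an average of 0.794% over all splits. The median gene lay 0.15 lower in ET-type (-0.15); with median-ratio rescaling 35 genes passed, 10 higher and 25 lower, and quantile scaling gave 29, of which 34.5% were higher. PI3R6 passed with any single library left out and under every scaling. The other named genes each lost their call without 1 or more libraries, SAP25 only without L S0384 (adjusted p = 0.0565). It was lost for ABCA3 without L S0349 or S0384 (0.0531 to 0.0716), for CR2 without ET S0235 or L S0349, S0384 (0.0531 to 0.0716) and for GIMA5 without ET S0235 or L S0349, S0355, S0384 (0.0529 to 0.0817). For TB10C it was lost without ET S0235, S0242, S0276 or L S0349, S0384 (0.0508 to 0.0768) and for GRAP without ET S0235, S0242, S0276 or L S0349, S0355, S0384, S0385 (0.0508 to 0.102). GALP, NCTR1 and CCL16 lost it without each library but L S0377 (0.0560 to 0.131, 0.0626 to 0.128 and 0.0647 to 0.128). The count of 62 became 4 without L S0384, 9 without L S0349, 14 without ET S0235, 15 without L S0355, 19 without ET S0276, 21 without ET S0242, 23 without ET S0326, 36 without ET S0309 and 213 without L S0377. In 1 fit of all libraries with the animal as replicate block, 718 lung genes passed.

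Macrophage genes lay -1.08 log2 relative to all genes, camera adjusted p = 3.49e-05 in ET-type lungs. None of the 6 lung list calls held with an estimated correlation: camera gave adjusted p = 0.239 with an estimated correlation for the mitochondrial genome, 0.709 for red cell genes and 0.836 for the others. Of 12 macrophage genes 0 passed over all genes by limma and 10 were lower adjusted over the list alone, CD14, the endotoxin co-receptor, at 6.44 ± 2.79 against 17.3 ± 6.65 TPM (-1.30 ± 0.30, adjusted p = 0.0952) and CSF1R at -1.14 ± 0.33. Antigen presentation genes lay -0.46 log2 relative to all genes, camera adjusted p = 2.98e-04, 2 of 19 lower adjusted over the list alone, with HG2A, the invariant chain of class II, at -1.20 ± 0.29. T and NK cell genes lay -0.40 log2 relative to all genes, camera adjusted p = 0.0177, and 0.106 to 0.312 without ET S0242 or L S0377. The B and plasma cell list was not called (adjusted p = 0.580). Genes of the mitochondrial genome lay 1.25 log2 relative to all genes, camera adjusted p = 4.96e-10, 8 of 9 higher adjusted over the list alone, with NU3M at 1.08 ± 0.26 and NU5M at 1.07 ± 0.29. These transcripts took 8.94 ± 4.27% of TPM in ET-type and 3.94 ± 0.601% in L-type lungs (exact permutation p = 0.0238, adjusted 0.119). Cholesterol synthesis genes lay 0.26 log2 relative to all genes, camera adjusted p = 0.00412, and 0.0815 without L S0385. Red cell genes lay 0.65 log2 relative to all genes, camera adjusted p = 0.0191, and 0.0675 to 0.174 without ET S0276, S0326 or L S0385. Lung marker genes were not called (-0.32, adjusted p = 0.0873); of 15, 1 was lower over all genes and 4 adjusted over the list alone.

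In spleens of ET-type animals, SLAF7, a receptor of NK and plasma cells, was among the lower genes and stood at 1.73 ± 0.718 against 9.83 ± 3.13 TPM (-1.98 ± 0.25, adjusted p = 0.0124), KLRG1, a receptor of effector T and NK cells, at 3.11 ± 1.59 against 13.5 ± 4.83 TPM (-1.82 ± 0.30) and UBS3B, a brake on T cell signalling, at 1.97 ± 1.14 against 9.82 ± 2.92 TPM (-1.91 ± 0.30). CTR1, a transporter of basic amino acids, stood at 3.72 ± 1.52 against 19.5 ± 6.04 TPM (-2.13 ± 0.27, adjusted p = 0.0124), CY24B, the catalytic part of the phagocyte oxidase, at 10.4 ± 6.74 against 38.8 ± 17.9 TPM (-1.99 ± 0.48) and PDK4, the fasting-induced kinase of pyruvate dehydrogenase, at 22.1 ± 15.5 against 76.6 ± 25.7 TPM (-1.91 ± 0.38). AT11A, TKTL1 and ALBU fell by 1.81, 1.94 and 2.21 on the log2 scale, ALBU by 1.40 (-1.40) without L S0377; so did CSGB (-2.59), a unit whose best hit was a bacterial curlin at 33.3% identity, so that its protein is unknown. Higher in ET-type were the calprotectin chains of neutrophils, S10A9 at 34.0 ± 25.8 against 6.46 ± 2.51 TPM (2.03 ± 0.43) and S10A8 at 5.98 ± 3.99 against 1.98 ± 0.807 TPM (1.12 ± 0.31), and BOLA2, of iron-sulphur cluster handling, at 77.1 ± 13.8 against 36.1 ± 1.99 TPM (1.06 ± 0.15, adjusted p = 0.0142). SMAGP, FBLN3, S2539, SNAI2, TNR12, HSPB7 and ID1 rose by 2.16, 1.52, 1.33, 1.22, 1.21, 1.17 and 0.86.

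By limma 5339 of 24007 genes passed in spleen, 167 higher and 5172 lower in ET-type, and the median gene lay 0.47 lower (-0.47). The number of calls fell with the scaling, and centring on the median by itself evens out their directions. With median-ratio rescaling 643 genes passed, 57.5% of them higher, and with quantile scaling 48, 52.1% of them higher. Of the 643, 374 had passed in the same direction before, and of the 48, 41. Named genes kept their direction under each scaling, and CTR1, SLAF7 and BOLA2 passed under each and with any single library left out. Of 2963 passing genes with an entry, 1849 had groups that did not overlap, 21 higher and 1828 lower. Over all genes with an entry the share was 19.1%, against an average of 0.794% over all splits. Haemoglobin transcripts took 21.4 ± 9.46% of TPM in ET-type spleens and 7.13 ± 6.77% in L-type (exact permutation p = 0.0317, adjusted over 5 tissues 0.0794). With haemoglobin left out and the rest rescaled, 1950 genes passed, 10.6% of them higher. The count became 41 without L S0377, 50 without L S0385, 112 without ET S0326, 254 without ET S0276, 730 without L S0384 and 2600 without ET S0242. The other named genes except CSGB then lost their calls for 1 or more of these libraries, at adjusted p from 0.0501 to 0.121.

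**Figure D4:**
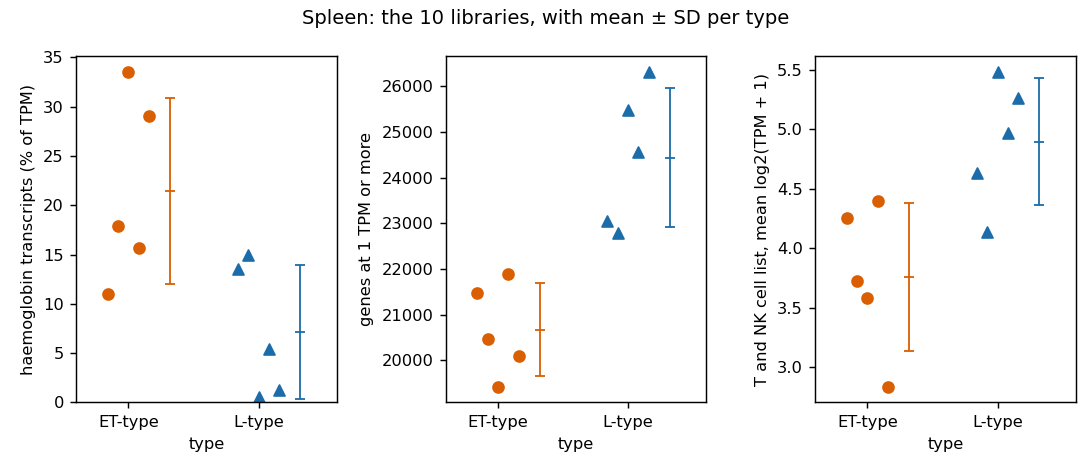
Haemoglobin share of TPM in percent, number of genes at 1 TPM or more, and mean log2(TPM + 1) of the T and NK cell list in each spleen library, with group mean and SD (n = 5 animals per type). ET-type spleens have more haemoglobin, fewer genes and less of the T and NK cell list, with overlap in haemoglobin and in the T and NK cell list.

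The red cell list lay higher in ET-type spleens, 2.53 log2 relative to all genes, camera adjusted p = 9.21e-11. With an estimated correlation no spleen list held: camera gave adjusted p = 0.302 with an estimated correlation for red cell genes, 0.624 for smooth muscle and matrix, 0.855 for the mitochondrial genome and 0.922 for T and NK cells and endothelium. Of 9 red cell genes 2 passed higher and 1 lower over all genes, and 6 and 1 adjusted over the list alone. HBA stood at 74124 ± 33797 against 20619 ± 18609 TPM and AHSP, a chaperone of alpha globin, at 2.75 ± 0.86. T and NK cell genes lay -0.79 log2 relative to all genes, camera adjusted p = 0.0228, and 0.0735 without ET S0326; 10 of 17 were lower over all genes and 12 adjusted over the list alone, with CD3G at 19.0 ± 8.64 against 58.7 ± 21.6 TPM (-1.62 ± 0.38) and CD2 at -1.48 ± 0.36. B and plasma cell genes were not called as a list (adjusted p = 0.0564), though 5 of 12 were lower over all genes and 12 adjusted over the list alone, with IRF4 at -1.41 ± 0.27 and CD79B at -1.75 ± 0.56. Smooth muscle genes lay 0.86 log2 relative to all genes, camera adjusted p = 9.22e-08, with desmin (DESM) at 0.68 ± 0.23 as the only member past the test. Matrix genes (0.25, adjusted p = 0.0115, and 0.112 without ET S0242), genes of the mitochondrial genome (0.32, 0.0179, and 0.0536 to 0.195 without ET S0326 or L S0355, S0385) and endothelial genes (0.43, 0.0280, and 0.0689 to 0.117 without ET S0235 or L S0385) were called higher relative to all genes. Their medians were -0.22, -0.15 and -0.04, below 0, with means of -0.09, 0.03 and -0.11; 2 matrix genes were lower over all genes. Of the genes that matter in pig-to-human grafting, 6 of 15 were lower over all genes and 7 adjusted over the list alone. B4GN2, which makes a carbohydrate antigen, stood at 6.24 ± 1.42 against 19.96 ± 7.33 TPM (-1.48 ± 0.26) and DAF, the complement decay-accelerating factor, at -1.17 ± 0.29; the list was not called (adjusted p = 0.305).

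Averaged over the 5 tissues of each animal, no gene with an entry passed in the fit of animal means. Genes named here had the smallest p, over all genes or within a called list. ACADV stood at 65.1 ± 9.81 against 124 ± 7.62 TPM (-0.76 ± 0.11, adjusted p = 0.0590). MLRV, the ventricular myosin light chain, had -1.32 ± 0.18 (adjusted p = 0.0590). This came largely from low values in lung (1.73 ± 3.46 against 20.7 ± 26.1 TPM, -2.47) and kidney (0.224 ± 0.222 against 6.02 ± 4.699 TPM, -2.12) and less from heart (-1.03). Myoglobin (MYG), S2534, ECHA and the cotransporter S12A7 had -0.82, -1.12, -0.76 and -0.69. The matrix proteoglycan LUM had 49.4 ± 18.2 against 19.6 ± 4.51 TPM (0.81 ± 0.16, adjusted p = 0.153), and BOLA2, PLAT5, CPXM1 and TB15C had 0.81, 0.40, 0.93 and 0.76. By limma 1 of 29796 units passed, a transcript without a protein hit that was higher in ET-type, Lymph.ET.NODE_5956 (4.07 ± 1.42 against 0.352 ± 0.192 TPM, 1.78 ± 0.17, adjusted p = 0.00725), named after its value was seen; 5060 had an unadjusted p below 0.05. Groups did not overlap for 4.69% of the genes with an entry, against an average of 0.794% over all splits, and the median gene lay 0.16 lower in ET-type (-0.16). The count became 5 without L S0349 or L S0385, 4 without ET S0309, 3 without ET S0235 or S0326, and 2 without ET S0242. In 1 fit of all libraries with the animal as replicate block, 967 passed. That fit takes the same correlation within animals, 0.114, for every gene. It can therefore be too favourable where the tissues of an animal vary together more than that.

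Fatty acid oxidation genes lay -0.35 log2 relative to all genes, camera adjusted p = 3.70e-08 across tissues, 13 of 19 lower adjusted over the list alone and 0 over all genes by limma. With an estimated correlation none of the 8 list calls across tissues held: camera gave adjusted p = 0.376 with an estimated correlation for fatty acid oxidation and the mitochondrial genome, and up to 0.879 for antigen presentation. Heart muscle genes lay -0.24 log2 relative to all genes, camera adjusted p = 0.00621, 7 of 14 lower adjusted over the list alone, and 0.0670 without ET S0309. Relative to all genes, red cell genes lay 0.85 higher (adjusted p = 3.22e-08), genes of the mitochondrial genome 0.42 (5.71e-06), proliferation genes 0.28 (9.49e-07), cholesterol synthesis genes 0.27 (9.36e-08) and matrix genes 0.26 (1.32e-04). Antigen presentation genes lay 0.19 higher (0.00482, and 0.189 to 0.287 without ET S0235, S0276). Without the kidney libraries 5 of the 8 list calls across tissues held and 3 no longer passed, while all 8 held without the spleen libraries.

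**Figure D5:**
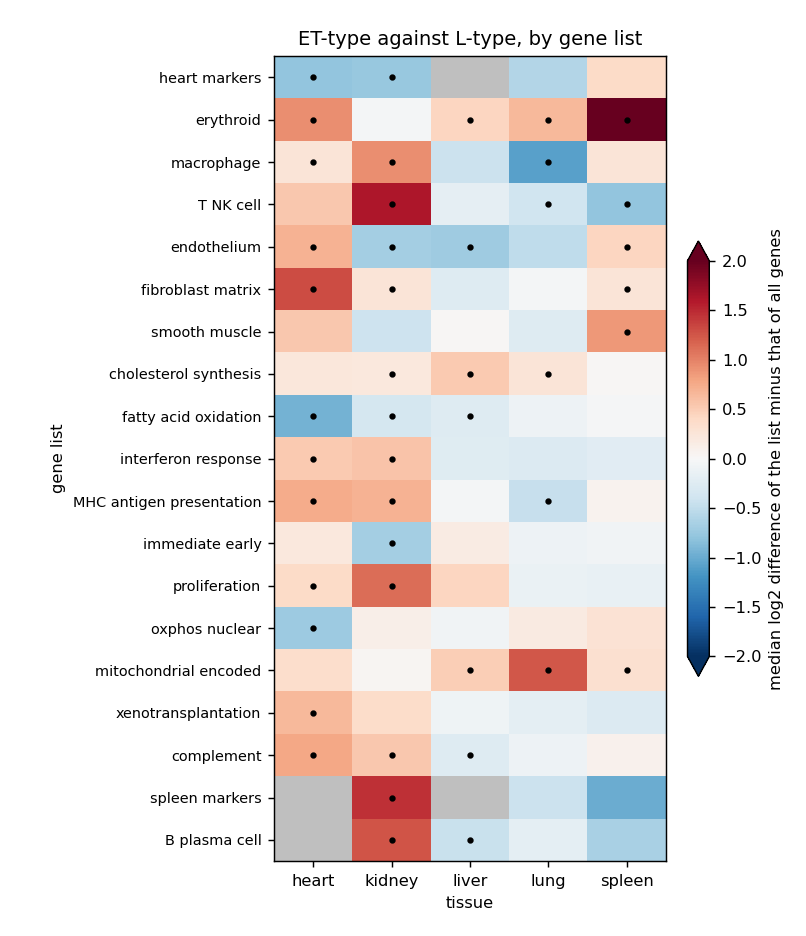
Median log2 difference (ET-type minus L-type) of each fixed gene list relative to all genes, by tissue. Shown are lists past an adjusted camera p of 0.01 in at least 1 tissue. Black dots mark an adjusted camera p below 0.05 and grey cells lists with too few measured members; no dot holds with an estimated correlation.

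Whether the type difference itself changed from tissue to tissue was tested within animals. SPA11, a serpin made by liver, had 34.8 ± 7.86 against 93.4 ± 21.9 TPM in liver (adjusted p = 4.94e-06), and PLAT5, a phospholipase and acyltransferase, had 57.4 ± 16.7 against 14.3 ± 7.202 TPM in liver (adjusted p = 8.10e-06). ANGL4, a fasting-responsive inhibitor of lipoprotein lipase, had 19.2 ± 18.6 against 66.9 ± 37.3 TPM in kidney and -1.58 on the log2 scale in lung, against 0.38 in liver and 0.35 in heart (adjusted p = 2.37e-04). CRIM1, which binds growth factors, had 2.25 in liver against -1.20 in kidney and -1.06 in spleen, and CEFIP, a muscle protein of the Z-disc, had 7.12 ± 1.78 against 21.8 ± 10.4 TPM in heart. In liver, DHB13, a lipid droplet enzyme, had 22.3 ± 23.3 against 276.3 ± 181 TPM (adjusted p = 7.21e-04), CPN2 58.2 ± 4.96 against 117 ± 17.8 TPM and GLYL2 11.4 ± 6.50 against 2.39 ± 2.30 TPM. DOXA2, which matures an airway oxidase, had 4.14 ± 1.16 against 15.9 ± 7.99 TPM in lung, and S115A 8.72 ± 4.53 against 2.27 ± 1.79 TPM in spleen. SPA11, PLAT5, CEFIP, CPN2 and S115A had no group mean above 0.0461 TPM in the other tissues, GLYL2 none above 0.4097 and DOXA2 none above 0.624. For these the interaction restates the difference in a single tissue, and only ANGL4, CRIM1 and, at up to 3.17 TPM, DHB13 were measured in others. By limma 1427 of 29796 genes passed, 694 of them with an entry. The tissue farthest from the rest was heart for 387 genes, spleen for 362, liver for 249, lung for 219 and kidney for 210. The type difference there lay below the gene's median over tissues for 168 of the 219 in lung and 176 of the 210 in kidney. The same held for 88 of the 249 in liver, 74 of the 387 in heart and nearly all in spleen. Lying below that median need not mean that ET-type was lower than L-type there. The count became 3061 without ET S0235, 2673 without ET S0242, 3264 without ET S0309, 739 without ET S0276, 327 without ET S0326, 471 without L S0349, 835 without L S0355, 493 without L S0377, 328 without L S0384 and 167 without L S0385, and 3792 without the kidney library of S0235 alone.

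Across genes, which are not independent replicates, the type differences of 2 tissues had a median Pearson r of 0.168 over 10 pairs of tissues, from 0.074 to 0.296. Other splits of the animals gave median values of 0.158 to 0.298 per pair, and 1 pair lay above its own. The permutation p of r ran from 0.357 to 0.96, and each adjusted p was 0.96. By covariance, which also counts the size of the differences, 7 of 10 pairs lay above the median of the splits, and lung and spleen, at 0.0655, above every other split (highest 0.0581; permutation p = 0.00794, adjusted 0.0794). Transcripts at 1 TPM or more in all 5 animals of one type and listed at 0 in all 5 of the other numbered 2 in heart, 2 in kidney, 0 in liver, 4 in lung and 6 in spleen, and 0 over all tissues. A HXK4 transcript was seen in ET-type hearts alone and a PGAP2 transcript in L-type hearts alone. In lung, a COX11 transcript (9.16 ± 3.48 TPM) was seen in ET-type alone and an INAVA transcript (8.99 ± 5.19 TPM) in L-type alone, and in spleen a KC1A transcript (12.7 ± 9.56 TPM) in L-type alone; all 5 were named after their values were seen. With 1 animal left out the counts ran from 2 to 7 in heart, 2 to 8 in kidney, 1 to 4 in liver, 5 to 13 in lung and 8 to 16 in spleen, as a smaller group is met more easily. Of 126 splits of the animals into 5 and 5, 22 gave as many in heart, 24 in kidney, 5 in lung and 2 in spleen, where another split reached 4, 9, 4 and 6.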

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

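The tests of the kidney library, of the spleen and of scale in the heart were chosen only after the result was seen; the test of a lower muscle share in the heart and the other splits of the samples were chosen before. A library counted as far from the rest where its gap to the nearest of its group was above 0.71 of the group's range (5 animals). This held in 26 of 234 groups tested, spread over 19 libraries, where chance picks about 1 in 20 groups, or 11.7.

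Among measures of whole libraries, the heart of L S0377 had 17334 genes at 1 TPM or more (others 19482 to 20246). Mitochondrial transcripts took 26.4% of TPM in the liver of ET S0326 (7.01 to 10.1%) and 5.10% in its spleen (2.94 to 3.26%), and haemoglobin took 0.0812% in its liver (0.00492 to 0.0243%). The kidney of ET S0235 had r = 0.633 with its own tissue (0.914 to 0.948), CD3Z at 511 TPM (5.56 to 22.8), OTULL at 67.9 (11.8 to 27.7) and KITH at 26.2 (2.94 to 4.48). In other kidneys, L S0384 had EGR1 at 219 TPM (39.8 to 61.3) and CPXM1 at 6.25 (0.833 to 2.40). In heart, VIME was 815 TPM in ET S0326 (369.9 to 483) and FINC 12.7 in L S0355 (5.0 to 6.26).

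In liver, L S0355 had CP2CI at 2041 TPM (others 225 to 489.9) and IDI1 at 1641 (299 to 483), L S0384 had MORC4 at 16.1 (6.64 to 8.83), ET S0309 had SPA11 at 48.8 (30.6 to 32.7) and ET S0242 had CP2E1 at 99.1 (0.441 to 15.7). IF2A was 2.26 TPM in ET S0276 and listed at 0 in the others. In lung, GALP was 2.38 TPM in ET S0242 (0.373 to 0.713), CSF1R 95.6 in L S0385 (32.4 to 46.5) and HG2A 321 in ET S0309 (717 to 857). In spleen, ALBU was 53.1 TPM in L S0377 (1.1 to 4.71) and 0.825 in ET S0309 (0.0937 to 0.214), HSPB7 41.9 in ET S0276 (16.4 to 21.0), S10A8 13.1 in ET S0326 (3.46 to 4.75) and SNAI2 4.04 in L S0384 (2.07 to 2.60).

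By the test of the interaction 1427 genes differed between tissues in their type difference, and the 10 with the smallest p are named. For 7 of these, SPA11, PLAT5, GLYL2, CPN2, CEFIP, DOXA2 and S115A, this restates a difference in the single tissue where they were expressed. Liver set apart SPA11 (adjusted p = 4.94e-06), PLAT5 (8.10e-06), GLYL2 (6.08e-04), CPN2 (6.08e-04) and DHB13 (7.21e-04), heart CEFIP (6.08e-04), lung DOXA2 (6.15e-04) and spleen S115A (6.08e-04). For ANGL4 (2.37e-04) and CRIM1 (6.08e-04) the mean differences had opposite signs in different tissues. The test asks only whether the differences are unequal. The positive ones of ANGL4, 0.35 in heart and 0.38 in liver, lay within the spread of the animals. Of 100 splits of the animals, the real one gave the highest number of genes, 1427, and the next gave 224. By that rule chance can be excluded for the count on unscaled values of all 50 libraries (1 of 100 as many). The count is not steady, though: it was 167 without L S0385, 327 without ET S0326 and 328 without L S0384. It was 313 without the spleen libraries and 3792 without the kidney library of S0235. No splits were run in these settings.

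The kidney library of ET-type S0235 held few kidney transcripts and many of lymphocytes. An exchange with a spleen library is argued against by TLX1, the factor that specifies spleen, at 0.0645 TPM where spleens have 54.2 to 111, with STF1 listed at 0 (spleens 3.58 to 9.08) and MADCA at 5.35 (32.2 to 111). A library of another animal is argued against, as it carried S0235's pattern of transcripts that are on or off by animal (share of matching transcripts 1). A kidney piece with added lymphoid cells is argued against by the median kidney marker at 0.281% of its level in the other kidneys. Lymphoid tissue other than spleen, such as a lymph node of that animal, may be what was sampled: transcripts assembled from lymph took 17.8% of the TPM outside mitochondrial and haemoglobin genes, the highest of 50 libraries (spleens 14.03 to 16.1%, other kidneys 8.04 to 11.3%). Over all TPM the share was 18.7%, and 3 libraries lay higher, kidney L S0355 (20.9%), kidney ET S0326 (19.6%) and heart ET S0309 (19.4%), so the rank holds on the first measure alone. A diseased kidney that kept its nephrons is argued against by the same marker value; one replaced by lymphoid tissue stays open.

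In spleen far more genes were lower than higher in ET-type, 5172 against 167. Haemoglobin taking part of the TPM total as the whole cause is argued against, since with haemoglobin left out the median gene still lay at -0.287 (-0.472 before) and 1950 genes passed. A shift of whole libraries in scale cannot be told apart from lower levels of most genes: TPM without spike-ins or counts gives no fixed point, and the share of calls higher in ET-type after median-ratio rescaling, 57.5%, is set by the centring and decides nothing. Blood content that differs between animals, beyond spleen, may add to it. HBB followed spleen HBB over the 10 animals in 2 of the other 4 tissues, heart (r = 0.856, rho = 0.830, permutation p = 0.00142 and 0.00439, adjusted 0.00284 and 0.00896) and lung (r = 0.905, rho = 0.830, permutation p = 7.20e-04 and 0.00448, adjusted 0.00284 and 0.00896), and r was 0.632 and 0.691 without S0377 and S0385. In kidney r was 0.414 and rho 0.491 (permutation p = 0.228 and 0.155, adjusted 0.304 and 0.206; 0.175 without both), and in liver r was -0.117 and rho 0.103 (permutation p = 0.746 and 0.786, adjusted 0.746 and 0.786; 0.561 without both); a difference of the types in spleen tissue itself stays open, untested.

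In heart, muscle and fatty acid oxidation lists were lower and the matrix list higher in ET-type. A lower share of muscle cells as the sole cause was predicted to raise other cell types alike. The mean of the matrix list rose above that of the macrophage list by 0.735 (exact permutation p = 0.0397), which goes against that prediction. It does not settle the question, since the added 1 TPM compresses the lower macrophage list more. Matrix was also not compared with endothelium or red cells, and other cell types need not rise alike. A lower muscle share therefore stays open. By animal, fatty acid oxidation genes had a mean of 5.06 ± 0.449 against 5.89 ± 0.256 (exact permutation p = 0.00794), matrix genes 4.86 ± 0.521 against 3.69 ± 0.556 (exact permutation p = 0.00794), heart muscle genes differed by -0.55 (exact permutation p = 0.0952), endothelium by 0.81 (0.0556), macrophages by 0.44 (0.0635), T and NK cells by 0.33 (0.0397) and red cells by 1.07 (0.0238). A shift of whole libraries in scale would move both lists the same way and is argued against as the whole cause, as the fatty acid oxidation mean differed by -0.836 and the matrix mean by 1.17, before any rescaling. Also open are the place in the heart from which the piece was taken, blood content, and a difference of the types in fat use or matrix, none of which was tested.

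Other splits of the 10 animals into 5 and 5 show how far chance can be excluded for the counts of genes. On unscaled values it can for lung (62, next 12) and for spleen (5339, next 40), each with 1 of 100 as many. The splits were not run on rescaled values, where median-ratio and quantile scaling gave 35 and 29 genes in lung and 643 and 48 in spleen. The spleen outcome thus includes the shift of most genes, which cannot be told apart from scale. With 1 library left out, though, the lung count fell as low as 4 and the spleen count as low as 41. For heart (5 genes) 3 of 100 splits gave as many, a share at which chance can be excluded, but another split gave 54, 31 others called at least 1 gene and the count was 0 without any of 5 libraries, so the heart count is not secure as an effect of type. For kidney, with 0 genes, the comparison decides nothing, since any split gives as many (100 of 100, highest other 5). Chance cannot be excluded for liver (2 genes, 14 of 100, highest other 23) or the mean over tissues (1 gene, 41 of 100, highest other 18). By genes with an unadjusted p below 0.05, though, the mean over tissues had 5060, with 1 of 100 splits as many and 3464 as the highest other. By the same measure spleen had 10605 (1 of 100, highest other 8306), heart 4670 (2, 5554) and lung 4729 (2, 6140). Kidney had 2301 (9, 5607) and liver 1412 (20, 3722), shares at which chance cannot be excluded. These numbers are also of unscaled values. With median-ratio and quantile scaling they were 6195 and 5248 in spleen and 2898 and 2823 for the mean over tissues. In heart they were then 5049 and 4977, and in lung 4464 and 4539, with no splits to set beside any of them. By adjusted p, another split called several times the real count in heart, liver and the mean over tissues, as a structure of the samples other than type would give. This was not tested. For the number of lists chance cannot be excluded in any fit: heart had 13 (6 of 100 splits as many, highest other 16), kidney 18 (21, highest other 21), liver 8 (37, highest other 15), lung 6 (74, highest other 17), spleen 6 (60, highest other 14) and the mean over tissues 8 (78, highest other 19). For genes higher in a tissue, relabelling tissues gave at most 1600 for heart (real 1356, 2 of 100 as many), 1834 for kidney (2019, 1), 3891 for liver (2031, 2), 743 for lung (6277, 1) and 2483 for spleen (2103, 2). At these shares chance can be excluded for each by the rule set beforehand. As tissue took 61.7% of the variance and the median relabelling gave 0, this outcome was nearly certain and says little about the size of the counts. In heart, liver and spleen another relabelling counted more genes than the real labels.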

How the results depend on the processing

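Leaving out haemoglobin, the kidney library of S0235, the kidney libraries or the spleen libraries were the settings chosen only after the result was seen. Where no reason is given, the cause was not tested. Of 103 named-gene results 15 kept direction and side of the threshold in every setting, and no named gene changed direction. Of the 103, 95 kept their side with a pseudocount of 0.1, 92 without a filter, 102 with robust limma, 82 with median-ratio rescaling (20 no longer passed) and 71 with quantile scaling (31 no longer passed); 84 of 89 did with a mean of at least 5 TPM, 91 of 100 with mitochondrial and the 10 highest genes left out, and 86 of 90 without haemoglobin. With 1 library left out, 825 of 1030 named-gene results kept their side, 177 no longer passed and 28 newly passed. Of 59 called lists, 53 held with median-ratio rescaling and 51 with quantile scaling, and 498 of 589 results held with 1 library left out. Camera with an estimated correlation called 0 lists. Fry called 23 lists, and 11 of them were among the 59 with the same direction. The kidney marker list in kidney turned from a call to no difference without ET S0235 (-0.0316), and ranged to -1.70 without ET S0242; the library's own low kidney markers account for that.

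Counts of genes moved as follows. A pseudocount of 0.1 gave 0 in heart, 1 in kidney, 19 in lung, 0 across tissues and 761 for the interaction. No filter gave 3 in heart, 1 in kidney and 12 across tissues. A mean of at least 5 TPM, which tests fewer genes, gave 1 in heart, 1 in liver, 15 in lung, 2691 in spleen, 0 across tissues and 542 for the interaction. A fold of at least 2, a stricter rule, gave 2038 in spleen. Median-ratio rescaling gave 35 in lung, 643 in spleen, 860 for the interaction, and 2497 heart, 3187 liver and 2927 lung genes. Quantile scaling gave 29 in lung, 48 in spleen and 661 for the interaction. Mitochondrial and the 10 highest genes left out gave 38 in lung, 1862 in spleen and 2 across tissues. Without haemoglobin spleen had 1950, and with median-ratio rescaling on top 625, and lung 35. Single transcripts gave 8 in heart, 4 in liver, 35 in lung, 5 across tissues and 2152 for the interaction. The interaction had 313 genes without the spleen libraries and 3792 without the kidney library of S0235, and the mean over tissues 3 without the kidney libraries. A log2 difference of at least 2, a stricter rule, left 776 heart, 924 kidney, 1315 liver, 2733 lung and 1172 spleen genes; L-type libraries alone gave 4203 for kidney and 3437 for spleen.

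The animal as replicate block in 1 fit of all libraries, which pools the spread of tissues, gave 718 genes in heart, 1369 in kidney, 374 in liver, 718 in lung and 967 across tissues; the interaction had 540 with no replicate block. The consensus correlation within animals, 0.114, was used for every gene, so the 967 may include genes whose tissues vary together more than that. The block changed no other count by more than 1.5 times. Of 103 named genes 40 newly passed with it and 11 no longer did.

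With 1 library left out, the count ran from 0 to 2162 in heart, 0 to 3 in kidney, 2 to 15 in liver, 4 to 213 in lung, 41 to 6179 in spleen, 1 to 5 across tissues and 167 to 3264 for the interaction. Transcripts on in one type and listed at 0 in the other ran from 2 to 7 in heart, 2 to 8 in kidney, 1 to 4 in liver, 5 to 13 in lung and 8 to 16 in spleen. At 0.5 TPM or more they were 4 in heart and 1 in liver, and 5 in kidney without the library of S0235. The median number of genes per library was 22378 at 1 TPM, 25897.5 at 0.5 TPM, 12122 at 5 TPM, and 33488 for transcripts in place of genes. The spleen markers in kidney without S0235 gave no value, as too few were measured. Depth could not be weighed, as no counts were given.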

Other observations

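The tests of feeding state and of PDK4 were chosen only after the result was seen; the tests of the transcripts that are on or off by animal were chosen before. All of the genes in this part were named after their values were seen.

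PDK4, which spares glucose by shutting the pyruvate dehydrogenase complex in fasting, had a lower mean in ET-type animals in 5 of 5 tissues. Kidney, spleen and liver prompted the look and all tissues come from the same 10 animals, so a state of the whole animal cannot be told apart from differences in single tissues. It stood at 11.7 ± 11.07 against 81.9 ± 66.3 TPM in kidney (-2.90, exact permutation p = 0.0159), 18.5 ± 20.3 against 82.1 ± 42.8 in liver (-2.55, exact permutation p = 0.0238) and 44.1 ± 44.5 against 201 ± 207 in heart (-2.04, exact permutation p = 0.0317). In spleen it stood at 22.1 ± 15.5 against 76.6 ± 25.7 TPM (-1.91, exact permutation p = 0.00794) and in lung at 53.6 ± 15.8 against 84.1 ± 31.6 (-0.58, exact permutation p = 0.135). Adjusted over the 5 tissues, p was 0.0397 in the first 4 and 0.135 in lung.

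A candidate explanation is that the types differed in feeding state at sampling. Of 10 genes that fasting raises, HMCS2 and FGF21 had no transcript with that entry, and the other 8 had lower means in ET-type (-0.62, exact permutation p = 0.0238), with tyrosine aminotransferase (ATTY) at 370.3 ± 239 against 1247 ± 1128 TPM and serine dehydratase (SDHL) at 85.2 ± 36 against 294 ± 243. Of 12 genes that feeding raises, with ACOD likewise absent, 11 had higher means (1.03, exact permutation p = 0.0476): glucokinase (HXK4) stood at 104 ± 71.5 against 26.4 ± 34.9 TPM, fatty acid synthase (FAS) at 281 ± 206 against 63.5 ± 68.3 and THRSP at 417 ± 212 against 87.3 ± 41.3. ELOV6 was the exception (49.6 ± 22.2 against 124 ± 21.7). ANGL4, which fasting also raises and which was in neither list, went the other way in liver (269 ± 104.4 against 204.3 ± 66.9 TPM, 0.38). The difference of both lists was -1.65 (exact permutation p = 0.0159). INSI1 and ERG1 are also members of the cholesterol list that prompted the look; without them, left out after the full lists were tested, the feeding genes had 1.16 (exact permutation p = 0.0159) and the difference was -1.78 (exact permutation p = 0.0159). Most of the other feeding genes, FAS, THRSP, SCD, ACACA, ACLY and ELOV6 among them, belong to the fixed lipogenesis list, which was not called in liver. Among the fasting genes CR3L3 (-0.06), IBP1 (-0.13) and CPT1A (-0.27) differed least, and ATTY (-1.48) and SDHL (-1.46) most. The labels give no feeding times, so an inherited difference in metabolism stays open, as does the order in which the animals were sampled.

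Each animal carried its own set of silent transcripts. Of 11302 transcripts with a clear state (1 TPM or more, or 0.1 TPM or less) in all 50 libraries, 91 were on or off in the same animals in all 5 tissues, 72 of them with an entry, among them transcripts of TIMP3, LEG1, LAP4B, TSN3, CTDS2, SPP and IGBP1. Chance coincidence between tissues is argued against, as 1000 shuffles of animals within tissues gave at most 3. All 50 libraries matched their own animal best (0.964 or more, against at most 0.821 for another animal). Alleles that the assembly kept as separate transcripts may give such a pattern. None of the 91 (0) set all ET-type apart from all L-type animals. Animals of one type shared 0.669 of the states and animals of different types 0.664 (exact permutation p = 0.365, 46 of 126 splits as high), so whether animals of one type are closer relatives cannot be told apart from chance with 10 animals.

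A transcript of tissue factor (TF), the starter of clotting, was higher in every ET-type than in every L-type animal in each tissue, 2.62 ± 3.79 against 0.00843 ± 0.0159 TPM over all libraries, at 79.5% identity to its entry. Its lowest ET-type value was 0.132 TPM. A DIK1A transcript (0.769 ± 0.346 against 0.186 ± 0.0774 TPM) and Lymph.ET.NODE_5956 did the same, and a NUDC3 transcript (14.6 ± 12 against 45.9 ± 23.3 TPM) and 2 without a protein hit did the reverse. These were found among 57085 transcripts. Other splits of the animals were not counted for this rule, so chance cannot be judged for them. A transcript whose best hit was KDM5D, at 59.4% identity, was listed at 0 in all 5 libraries of ET S0242, ET S0326 and L S0349, and had a mean of 5.32 to 9.06 TPM in the other 7 animals, of which 4 (S0235, S0276, S0309 and S0385) had 1 library at 0. The mean log2 of 12 genes that escape X inactivation was 4.54, 4.32 and 4.60 in these 3 animals and 4.45 to 4.92 in the other 7. Sex is not in the labels and was not inferred.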
